A study of Homo sapiens with 3 samples.

How the data were processed

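Total RNA of KYSE180 cells was labelled with biotin using a 3' IVT kit and hybridised to oligonucleotide arrays, per the labels' protocols, with 1 array for each of control, HOTAIR vector and HOTAIR siRNA. The deposited values are log2 probe set signals made with RMA, per the submitters' processing notes, and the log2 scale was taken from their range since the file states none. The version and settings of RMA, the chip definition and the background step are not given in the sources used here. RMA normally makes the quantiles of probe intensities equal before it summarises them, so quantiles of probe sets need not be exactly equal. The quartiles of probe sets were 3.72 and 7.35 in control, 3.58 and 7.55 in vector and 3.62 and 7.48 in siRNA cells. RMA summarises several probes per probe set and compresses differences near the background, so folds of dim genes are understated.

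The file held 49293 probe sets. A table of the platform's annotation gave 1 gene symbol for 44988 of them and several for 1832, and did not list 2473. Entrez identifiers were found in a RefSeq gene table for 44961 probe sets, and 0 symbols changed. A gene was represented by its probe set with the highest mean over the 3 arrays, among probe sets with 1 symbol, which gave 18132 genes. Genes were kept where that mean was at or above the median of all probe set means (5.28), which left 10917. No coordinates were used, and the RefSeq table served only for names and for which of the genes kept neighbour each other.

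The groups came from the sample labels. For each pair of arrays the log2 difference per gene was taken, and genes at least 2-fold apart were counted by direction. With 1 array per group no test was made. Genes with one array in the middle were counted at 1.5-fold on each side. For gene lists, 35 lists of 754 genes were fixed before the data were examined, of which 688 genes were measured and 534 kept, and 15 were present only on probe sets with several symbols. Each list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. The rule for named genes was also fixed before the data were examined. It took the 12 largest differences in each direction of each comparison, the 10 largest in each direction with the control in the middle, HOTAIR and WIF1, and the members of each list past 2-fold or else the 2 most different. HOXC11 and HOXC12 were added as neighbours of HOTAIR. The relation between the comparisons with control was set beside simulated arrays without effects that shared a control, with noise from the spread of probe sets.

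The steps were tested on simulated arrays, with the noise of each comparison set from its own spread of probe sets. Of 10917 genes, 200 were changed by 2 on the log2 scale. For vector minus control 100% were recovered and 56 unchanged genes passed 2-fold, for siRNA minus control 99.5% and 127, and for vector minus siRNA 100% and 0. A change of 2 lies well past the 2-fold cut at this noise, so high recovery was built in. The noise left out variation between arrays and cultures, so these counts are not error rates for the genes found below. Alternatives were other fold thresholds, no filter or a filter at the 75th percentile, and the mean over probe sets. Others were repeated quantile normalization, applied to probe set values, and cyclic loess (span 0.4, 3 cycles). Another left out probe sets open to cross-hybridisation, taken as those with names ending in _x_at or _s_at. The ending _s_at can also mark probes shared by transcripts of the same gene. A change on leaving them out therefore need not reflect cross-hybridisation. Differences centred on their median, and vector minus siRNA in place of vector minus control, were chosen after seeing the data. Spike-in and RNA quality probe sets numbered 0 among those used, so neither spike-in centring nor ratios of 3' to 5' signal could be computed. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.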

Results

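Gene expression was measured in KYSE180, a human oesophageal squamous cell carcinoma line, on 3 oligonucleotide arrays with 1 array per group. The groups were control cells, cells transfected with a vector carrying the long non-coding RNA HOTAIR, and cells transfected with a mixture of siRNAs against HOTAIR at 100 pmol, with RNA taken 48 h after transfection. The title and cell line field of the siRNA sample name KYSE180, while its source name refers to a HOTAIR cell line, and KYSE180 was taken for all 3 samples. If that source name were right, every siRNA comparison would also be one between cell lines. The control is labelled only as control, and whether it received a reagent or a negative-control siRNA was not stated for that sample. The vector was delivered with Polyfect and the siRNAs with Lipofectamine2000, so the arms differed in reagent and in the kind of nucleic acid. Median log2 signals were 5.27 on the control array, 5.23 on the vector array and 5.25 on the siRNA array. With 1 array per group no difference has a replicate check and no p-value is given. The only error that could be measured was the spread between probe sets of one gene, an SD of 0.36 (log2) for vector minus control, 0.39 for siRNA minus control and 0.21 for vector minus siRNA over 5982 genes. The number of arrays limits the precision of every value below.

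HOTAIR, the manipulated RNA, is transcribed from the HOXC locus and binds the repressive chromatin complex PRC2. The table of probe set genes named 0 probe sets for HOTAIR, so its level was not analysed here and neither arm could be checked by its target. HOXC11, which flanks HOTAIR, had log2 signals of 5.71 in control, 5.01 in vector and 5.42 in siRNA cells, and HOXC12, on its other side, had 3.69, 3.40 and 3.51, below the level of most probe sets. Among 8 HOXC genes and 4 HOXD genes above the filter, none differed 2-fold in any comparison. Of 15 genes for PRC2, its accessory proteins and the LSD1 complex, the PRC2 core gene SUZ12 was higher than control by 2.51 (log2) in vector and 2.21 in siRNA cells, and MTF2 by 1.38 and 1.51. AEBP2 was higher by 1.07 in siRNA cells (0.94 after repeated quantile normalization), and none of the 15 differed 2-fold between the arms.

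The first comparison asked which genes differed between HOTAIR vector cells and control cells. Interferon-stimulated genes, which encode antiviral effectors and RNA sensors, were higher in vector cells. Of 34 such genes above the filter, 26 were at least 2-fold higher and 0 lower, with a median log2 difference of 2.93, above all 10000 random lists matched on expression (percentile 100). IFI27 was 95.5-fold higher (log2 6.58), IFI44 6.09, DDX60 5.87, SAMD9 5.41, IFIT3 4.77, the RNA sensor gene RIGI 4.66, OAS1 3.73, MX1 3.57 and ISG15 2.99. Genes of extracellular matrix breakdown were lower. The stromelysin gene MMP10 differed by -7.41 (log2, from 11.14 to 3.74 on a single probe set), the collagenase gene MMP1 by -6.83 (from 10.32 to 3.49) and the matrix glycoprotein gene TNC by -5.30 (from 8.25 to 2.95). These vector signals lay near or below the lower quartile of that array (3.58), so the size of the differences is uncertain, and it was -5.41 for MMP1 without probe sets open to cross-hybridisation and -2.70 for TNC with the mean over probe sets.

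In the list of 23 matrix proteases, their inhibitors and related genes, 6 were at least 2-fold lower in vector than in control cells and 1 was higher, with a median of -0.63 (percentile 0.01). This median was -0.39 after cyclic loess and -0.44 after centring. Besides MMP10, MMP1 and TNC, the lower members were MMP13 (-3.33), MMP2 (-2.15) and SERPINE2 (-1.07), while ADAM9 was higher by 1.26. With the mean over probe sets MMP13 was at -1.49, MMP2 at -1.38 and SERPINE2 at -0.97. Genes of squamous differentiation split, with 4 of 20 at least 2-fold higher and 0 lower. These were S100A9 (3.76) and S100A8 (1.22), which encode the calprotectin subunits, and the cornified envelope genes SPRR3 (2.77) and SPRR1B (2.47). Of 29 genes of the G2/M phase, 10 were at least 2-fold higher and 0 lower, among them the spindle checkpoint kinase gene TTK (4.58), HMMR (3.83) and the mitotic kinase gene CDK1 (2.91). For 9 of these 29 genes the siRNA array was also at least 2-fold above control. The large differences outside the lists included higher SCEL (4.58), SLCO1B3 (4.38), IRAG2 (4.35) and ZBTB41 (4.29) and lower CXCL14 (-2.81), SDK2 (-2.59), DACH1 (-2.48) and LYPD1 (-2.38). With the mean over probe sets CDK1 was at 1.69, SLCO1B3 at 2.37, CXCL14 at -1.51, SDK2 at -1.55 and LYPD1 at -1.67, and IRAG2 was at 2.43 without probe sets open to cross-hybridisation. Ribosomal protein genes, 37 in number, and 31 genes of oxidative phosphorylation had 0 members past 2-fold in any comparison, although the oxidative phosphorylation median was 0.11 in vector minus siRNA (percentile 99.7).

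Over the 10917 genes above the filter, 1662 were at least 2-fold higher in vector than in control cells and 224 were lower, so 88.1% of these genes were higher. Repeating quantile normalization gave 1444 higher and 518 lower (73.6% higher). At a 1.5-fold threshold 54.1% were higher, so the share depended on the threshold. The median difference of all genes kept was -0.18, and cyclic loess moved it to -0.04, so small shifts near 0 have no fixed direction.

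**Figure D1:**
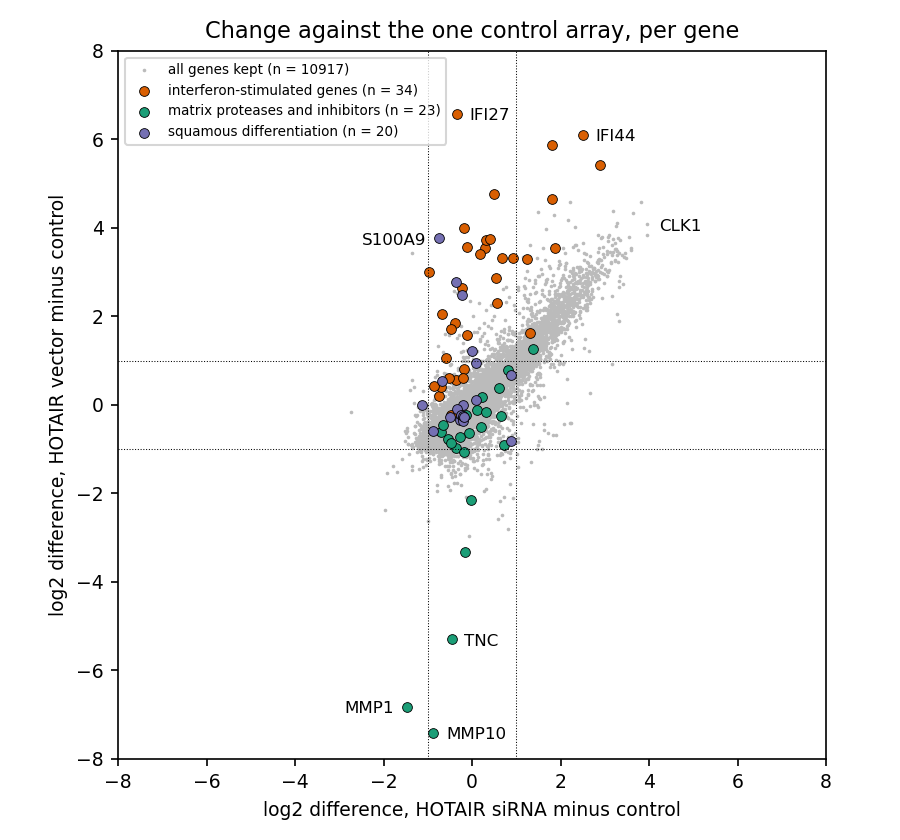
Each point is 1 of 10917 genes, with the log2 difference of HOTAIR siRNA minus control on the x axis and of HOTAIR vector minus control on the y axis, and dotted lines at 2-fold. Most genes lie along a shared diagonal that ends near CLK1, while interferon-stimulated genes such as IFI27 (6.58 on y, -0.35 on x) lie above it and the matrix genes MMP10, MMP1 and TNC lie below it.

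The second comparison asked which genes differed between cells given HOTAIR siRNAs and control cells. The interferon list was not shifted, with 7 of 34 members at least 2-fold higher, 0 lower and a median of -0.12 (percentile 58.8) whose sign turned when differences were centred on the median of all genes. The 7 were IFI44 (2.51), SAMD9 (2.90), IFIT5 (1.88), RIGI (1.81), DDX60 (1.79), GBP1 (1.31) and IFIH1 (1.25), and each was also at least 2-fold higher in vector cells. IFI44 was at 1.37 and IFIH1 at 0.66 with the mean over probe sets. IFI27 (-0.35) and MX1 (-0.13) were close to control, and ISG15 was -0.98. Genes of hypoxia and glycolysis were lower as a list, with a median of -0.65 over 23 genes, below all random lists (percentile 0), although only NDRG1 (-1.93) and PFKFB4 (-1.14) were 2-fold lower and BNIP3L was 2-fold higher. Without probe sets open to cross-hybridisation BNIP3L was at -0.090, and with the mean over probe sets PFKFB4 was at -0.55.

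Epithelial junction and identity genes had a median of -0.43 over 23 genes (percentile 0.22) in siRNA minus control, with the desmosomal genes going apart, PKP3 at -1.23 and DSG2 at 1.29. The list median was -0.33 after cyclic loess and -0.27 after centring. Of the matrix protease list 1 of 23 was 2-fold lower, MMP1 (-1.48), and 1 higher, ADAM9 (1.38, or 0.97 with the mean over probe sets). MMP10 (-0.87), MMP13 (-0.15) and MMP2 (-0.01) did not reach 2-fold. Of 29 G2/M genes 9 were higher and 1 lower, the anaphase activator gene CDC20, which missed 2-fold with the mean over probe sets (-0.81) and under every other scaling. The highest genes were the splicing kinase gene CLK1 (3.95), DCUN1D4 (3.94), TTK (3.82), the deubiquitinase gene USP16 (3.64), IFT80 (3.60), HSPA13 (3.59) and the replication origin gene ORC3 (3.54). All of these were also higher in vector cells, by 4.08, 3.83, 4.58, 4.34, 3.50, 3.53 and 3.79 in the same order. The sizes depended on the probe sets, since DCUN1D4 was at 1.29 in siRNA cells without probe sets open to cross-hybridisation, and CLK1 was at 2.97, USP16 at 2.93, ORC3 at 2.36 and HSPA13 at 1.78 there with the mean over probe sets. The lowest were the lipase gene CEL (-2.73), LYPD1 (-1.96), NDRG1, P2RY2 (-1.79) and TNFRSF12A (-1.69), and of these CEL was near control in vector cells (-0.17).

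In all, 1623 genes were at least 2-fold higher in siRNA than in control cells and 202 lower (88.9% higher), against 1472 and 408 (78.3% higher) after repeated quantile normalization. At a 1.5-fold threshold 55.9% were higher. The median of all genes kept was -0.17, or -0.01 after cyclic loess.

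The third comparison set the HOTAIR vector against the HOTAIR siRNAs, without the control array. Interferon-stimulated genes were again higher in vector cells, with 28 of 34 at least 2-fold higher, all 34 above 0 and a median of 2.36 (percentile 100). IFI27 differed by 6.93, IFIT3 by 4.28, IFI6 by 4.19, DDX60 by 4.08, ISG15 by 3.97 and MX1 by 3.70. Matrix protease genes were lower in vector cells, with 6 of 23 at least 2-fold lower, 0 higher and a median of -0.47 (percentile 0). MMP10 differed by -6.53, MMP1 by -5.35, TNC by -4.84, MMP13 by -3.18, MMP2 by -2.14 and TIMP2, an inhibitor of matrix proteases, by -1.63. The vector signals of MMP10, MMP1, TNC and MMP13 were dim, so the sizes of their differences are uncertain. The sizes depended on the probe sets, with TNC at -2.26, MMP13 at -1.28 and MMP2 at -1.50 for the mean over probe sets, and MMP1 at -3.93 and TIMP2 at -0.90 without probe sets open to cross-hybridisation.

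Several other lists stood apart between the arms. Squamous differentiation genes were higher in vector cells, with 6 of 20 at least 2-fold higher, among them S100A9 (4.50), SPRR3 (3.12) and SPRR1B (2.69), and 1 lower, the keratin gene KRT1 (-1.70), and a median of 0.21 (percentile 99.8). Mesenchymal genes had a median of -0.43 over 11 genes (percentile 0.01), with 4 at least 2-fold lower in vector cells, COL6A1 (-2.42), MMP2, COL5A1 (-1.89) and the N-cadherin gene CDH2 (-1.40), although COL6A1 was at -0.52 with the mean over probe sets and -0.41 without probe sets open to cross-hybridisation. Basal squamous genes had a median of -0.38 over 12 genes (percentile 0) with none past 2-fold. Epithelial genes had a median of 0.28 (percentile 100) with only ELF3 past 2-fold (1.46). Of the 23 hypoxia and glycolysis genes 22 were above 0, with a median of 0.39 (percentile 100), and HK2, PFKFB4 and ANKRD37 were 1.35, 1.06 and 1.03, but 0.91, 0.40 and 0.57 with the mean over probe sets. Wnt ligands and receptors had a median of -0.26 over 23 genes (percentile 0.02), with 0 at least 2-fold higher and 4 lower in vector cells, FZD1 (-1.60), WNT11 (-1.58), WNT10A (-1.38) and FZD10 (-1.05, or -0.79 with the mean over probe sets). Genes reported in other work as induced by HOTAIR had a median of -0.38 over 6 genes (percentile 0.15), with 0 higher and MMP2 and CDH2 lower in vector cells. Genes reported as repressed by HOTAIR had a median of -0.063 over 4 genes (percentile 27.6), with none of these 4 past 2-fold. The filter kept only these of the 11 measured. It left out WIF1 (2.73 in vector and 5.71 in siRNA cells) and PCDH7 (4.03 and 5.63, with 2.71 in control), both lower in vector cells. The other members left out were not 2-fold apart between the arms. Replication-dependent histone genes, whose near-identical copies can share probes, had a median of 0.73 over 10 genes (percentile 100), with none past 2-fold. Outside the lists, the long non-coding RNA UCA1 was higher by 4.80, and DACH1 (-3.16), SDK2 (-3.17), CXCL14 (-3.62), MRC2 (-2.81) and NID1 (-2.80) were lower. With the mean over probe sets SDK2 was at -1.69, CXCL14 at -1.88, MRC2 at -0.83 and NID1 at -1.58. Altogether 189 genes were at least 2-fold higher and 202 lower.

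**Figure D2:**
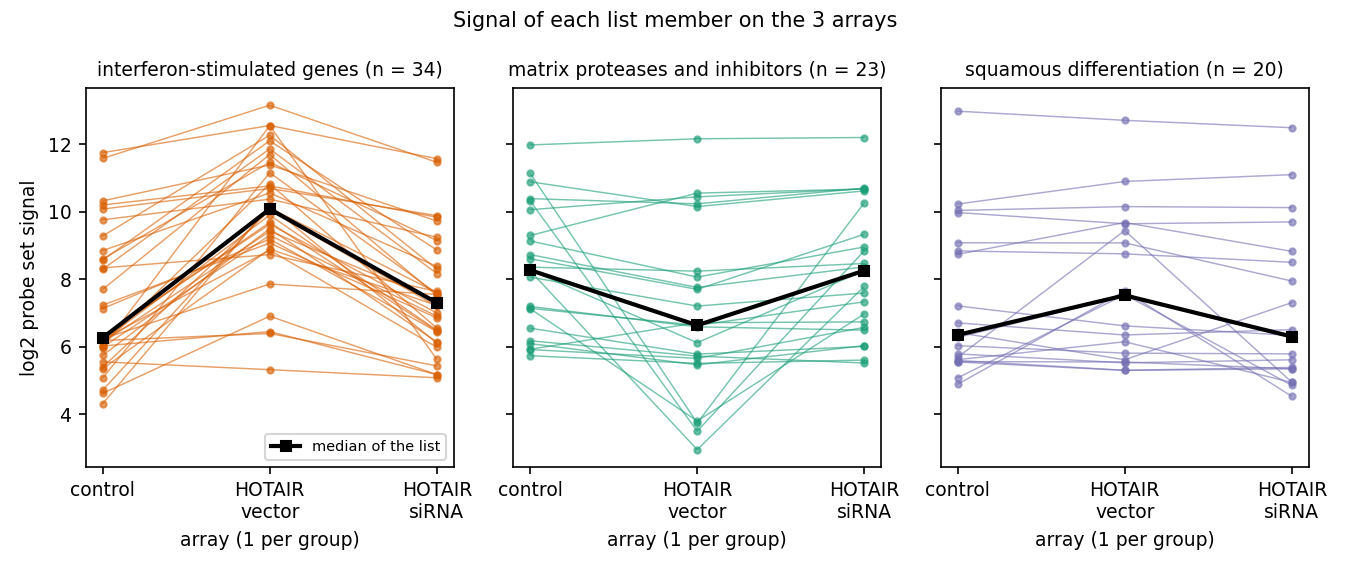
Log2 probe set signal (y axis) of every member above the filter on the control, vector and siRNA arrays (x axis), for interferon-stimulated genes (34), matrix proteases and inhibitors (23) and squamous differentiation genes (20), with 1 coloured line per gene and the list median in black. The interferon lines peak on the vector array, and a few matrix genes drop there, MMP10 to 3.74 and MMP1 to 3.49.

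**Figure D3:**
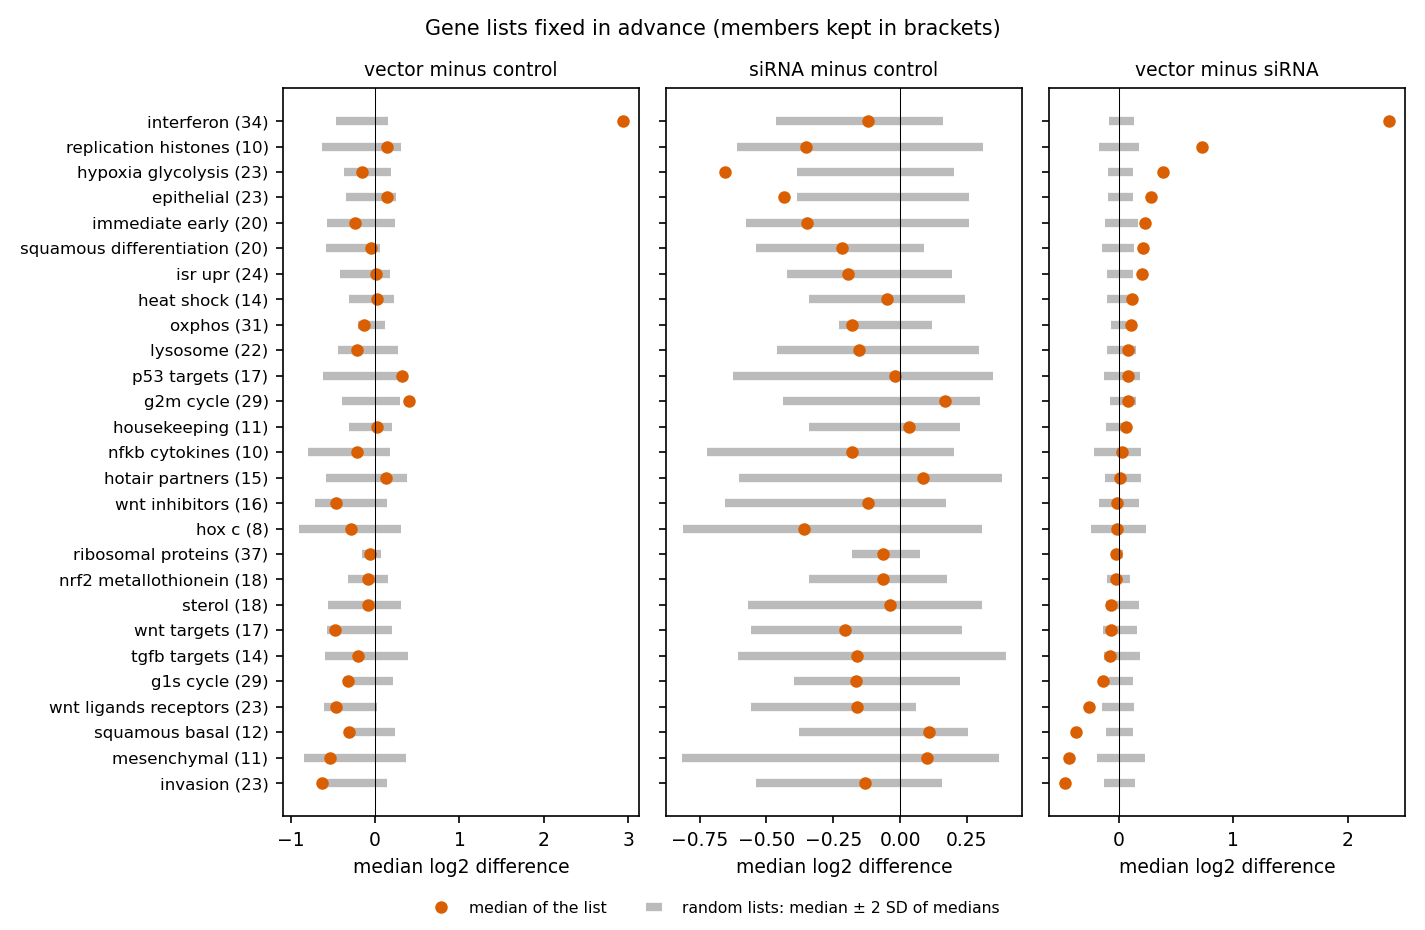
Median log2 difference of each gene list with at least 8 members above the filter (orange points, members in brackets), with grey bars for the median of random lists matched on expression ± 2 SD of their medians, in 3 panels whose x axes differ in scale. Interferon genes lie far to the right in both panels with the vector array (2.93 and 2.36), and hypoxia and glycolysis genes lie to the left for siRNA minus control (-0.65).

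A set of genes had the control between the arms, as opposite manipulations of one RNA would place it. At 1.5-fold on each side, 16 genes were highest in vector and lowest in siRNA cells, and 40 were highest in siRNA and lowest in vector cells. The first set included UCA1 (3.43 against control in vector and -1.37 in siRNA cells), ISG15, S100A9, ELF3, GDF15 (1.32 and -0.77) and NECTIN4 (0.75 and -0.79). The other set included DMRT1 (-1.30 and 1.34), DAPL1 (-1.41 and 1.05), TUBA1A (-2.10 and 0.92) and the collagen genes COL5A1 (-1.01 and 0.88) and COL6A1, the last at -0.040 for siRNA minus control with the mean over probe sets. DMRT1 was then at -0.66 and 0.070, which leaves the control no longer in the middle by this rule. NECTIN4 in vector cells (0.21) and GDF15 (-0.42), ELF3 (-0.54) and COL5A1 (0.40) in siRNA cells also missed 1.5-fold with the mean over probe sets, and S100A9 missed it in siRNA cells after cyclic loess (-0.51). Of those named, UCA1, DAPL1, TUBA1A and ISG15 stayed past it under each scaling and with the mean over probe sets. With the siRNA array in the middle, 184 genes ran from vector down to control and 11 from control down to vector, and with the vector array in the middle 53 ran from siRNA down to control and 7 the other way. The control was thus in the middle in fewer genes than either other array. Reading these counts as an excess or a lack would need 3 arrays that vary alike. The control array held 77.2% of the array-specific variance, against 19.8% for vector and 3.01% for siRNA. An array that stands apart is seldom in the middle. The counts therefore cannot show whether opposite manipulations added genes of this order. At 2-fold on each side, 1 and 3 genes were left with the control in the middle.

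Wnt pathway genes were compared because published work on HOTAIR in oesophageal cancer cells concerns the secreted Wnt inhibitor WIF1, so WIF1 is not independent evidence. WIF1 had log2 signals of 3.14 in control, 2.73 in vector and 5.71 in siRNA cells, on 1 probe set whose mean lay below the filter of 5.28. The control and vector signals lay below the lower quartiles of their arrays (3.72 and 3.58), so no fold is given and their order is not read. The siRNA signal lay above that filter level, so WIF1 was higher in siRNA than in control and vector cells, with 1 array each. Among 16 other Wnt inhibitors, DKK3 was lower (-2.97) and DKK1 (1.12) and SOSTDC1 (1.65) higher in vector than in control cells, and SOSTDC1 was also higher in siRNA cells (1.39). With the mean over probe sets DKK3 was at -1.27 and SOSTDC1 at 0.96 and 0.68, and DKK1 at 0.95 after repeated quantile normalization. Of 23 Wnt ligands and receptors, 4 were higher in vector cells, FZD6 (2.26), LRP6, FZD3 (1.42) and FZD5 (1.08), and 5 lower, WNT11 (-1.82), WNT10A (-1.78), FZD1 (-1.35), FZD10 (-1.13) and WNT3A (-1.09). FZD6, LRP6 and FZD3 were also higher in siRNA cells, by 2.34, 1.81 and 1.49. LRP6 was at 0.11 and 0.051 and FZD3 at 0.88 in siRNA cells without probe sets open to cross-hybridisation, FZD5 at 0.20 and WNT3A at -0.57 with the mean over probe sets, and FZD10 at -0.95 after centring. Of 17 Wnt target genes, whose median was -0.48 in vector minus control (percentile 2.01), none differed 2-fold from control in either arm, and SOX4 was lower in vector than in siRNA cells (-1.09). The vector minus control median of these 17 genes was -0.30 after cyclic loess and -0.29 after centring.

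Genes such as CLK1, TTK and USP16 were higher than control in both arms, and the comparisons with control were related across genes. Of the genes at least 2-fold higher in each, 1387 were shared, 83.5% of those for the vector, and 26 lower genes were shared. Arms with no effect that share a control array would share 16.9 and 16.4 genes by the simulation below, and independent lists of these sizes 247 and 4.14. The simulation leaves out effects and the independent lists leave out the shared control, so neither excess measures a shared effect. Only 1 gene, UCA1, was 2-fold higher in vector and lower in siRNA cells, and 3, DAPL1, DMRT1 and SOBP, were the reverse. These 3 each missed 2-fold on at least one side under some alternative, DAPL1 in siRNA cells after repeated quantile normalization (0.96), DMRT1 as given above and SOBP with the mean over probe sets (-0.44 and 0.53), while UCA1 kept both under every alternative run. Across genes, which are not independent replicates, the differences correlated with Pearson's r of 0.875 and Spearman's rho of 0.828. A control array shared by arms with no effect gave r of 0.855 when noise was set from the spread of probe sets, and 0.499 with equal noise on each array. That spread came from these same differences and gave a noise SD of 0.35 for control, 0.096 for vector and 0.18 for siRNA. It can hold part of a real departure of the control array. The value of 0.855 is therefore no independent expectation, and its nearness to 0.875 does not show a lack of effects. The covariance was 0.677 against a simulated 0.121, a difference of 0.556, and part of the excess may come from the single control array, which could not be split. Signals of the vector and siRNA arrays correlated at 0.988 over all probe sets, and those of control with each at 0.954 and 0.962.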

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

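A few probe sets outside the gene comparisons were higher on the vector array, at no larger share than among the genes kept (143 of 10917, 1.31%). Of 1071 probe sets absent from the gene table and above the filter, 12 were at least 2-fold higher on the vector array than on both others (1.12%), and of 842 with several gene symbols 4 were (0.475%).

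The tests of cyclic loess on the control array and of shuffled gene orders for the matrix genes were set before their values were seen, and all other tests below were chosen or redefined after results were seen. The control array stood apart from both transfected arrays, with 77.2% of the array-specific variance, against 19.8% for vector and 3.01% for siRNA, and 1387 genes at least 2-fold lower than on both. Intensity-dependent scaling is argued against as the whole cause, since 100% of these genes stayed past 2-fold after cyclic loess. Cyclic loess raised the median differences from control, though, which moves such genes away from the threshold. Repeated quantile normalization lowered those medians and left 1444 (vector) and 1472 (siRNA) genes 2-fold higher than control, against 1662 and 1623. Probe-dependent signal loss stays open, since 65.5% of the other probe sets of these genes were also 2-fold higher in both arms, and a first test that would have counted against it (an intraclass correlation of 0.846 between probe sets) ran over a wider set of genes. A control culture with another karyotype also stays open, since differences of neighbouring genes went together (SD of medians over 50 neighbours 3.67 times that of shuffled orders for vector minus control, at most 1.21 in 1000 shuffles), and the neighbours of 1353 of these genes had a median of 0.43 (95th percentile 1.02) against 1.76 for the genes themselves. An effect of transfection or culture on both arms cannot be told apart from a feature of that array for the 1387 genes, since 1 control array was analysed, and GC content was not used here.

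The higher interferon-stimulated genes of the vector array were not explained by the control array, since 82.4% of the list was at least 2-fold higher than on the siRNA array too. For immune cells in the vector culture, 0 of the 5 immune markers above the filter were 2-fold higher there than on both other arrays. That filter uses the mean of the 3 arrays and can drop a marker present on 1 array alone, so this test was weak. Of 15 markers measured, 4 lay above the filter level on the vector array, against 6 on the control array and 3 on the siRNA array. Their number was thus not raised over control. Plasmid DNA or reagent of the vector arm cannot be told apart from HOTAIR for the 28 members higher in vector than in siRNA cells, since no empty vector array was analysed here. An effect of HOTAIR on these genes therefore stays a hypothesis.

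The matrix genes low on the vector array were not explained by fibroblasts in the other cultures, since 0 fibroblast markers were above the filter on both and 2-fold lower on the vector array. For loss confined to a minority of the cells, 5 genes (MMP10, MMP1, TNC, MMP13 and MMP2) kept at most 22.5% of their control signal. The vector signals of all but MMP2 were too dim for exact shares, and with the mean over probe sets MMP13 (-1.49) and MMP2 (-1.38) kept more. These shares argue against such loss only if all cells expressed these genes alike, which bulk arrays cannot show. Loss in a subset of cells that held most of this signal stays open. A culture of another karyotype is argued against as the whole cause, since neighbouring genes went together 1.21 times as much as in shuffled orders, below the bound of 1.3 set beforehand by more than the SD of shuffled ratios (0.0463) but not by 2 SD, a choice made after the value was seen, and above all 1000 shuffles (at most 1.17). Copy loss of the regions around the 6 genes 2-fold lower than on the siRNA array is argued against too, since their 10 nearest neighbours above the filter had a median of -0.031 (lowest -0.072 for a gene) against -4.01 for the genes, although MMP10, MMP1 and MMP13 neighbour each other and count as 1 region. For vector minus control the neighbours' median was 1.12 for MMP10, MMP1 and MMP13, -0.55 for TIMP2, -0.12 for MMP2 and -0.018 for TNC. Around MMP10, MMP1 and MMP13 the control array thus differed regionally, which bears on the open question of its karyotype. Focal losses, secreted signals, a subline of like karyotype, the reagent and HOTAIR itself stay open and untested.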

How the results depend on the processing

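Most values of named genes kept their direction under the alternatives. Many list medians of siRNA minus control, and several of vector minus control, changed sign with the scaling. In siRNA minus control the matrix protease median went from -0.13 to 0.14 after cyclic loess. In vector minus control the squamous differentiation median went from -0.050 to 0.074. The interferon medians with the vector array kept their sign. Of the list median values 564 were counted as the same and 105 as moved. Centring on the median and leaving the control array out were chosen after seeing the data. Over all alternatives, 48 values for the comparisons stayed within 1.5 times and 43 did not; of named genes 4294 values stayed within the spread between probe sets, 259 moved and 7 past 2-fold changed sign, while 88 changes of sign of values under 2-fold are counted in the first 2 groups. At 1.5-fold, 2499 genes were higher and 2117 lower for vector against control, 2492 and 1964 for siRNA against control, and 517 and 540 for vector against siRNA; at 3-fold these were 890 and 32, 791 and 5, and 69 and 65. With 2-fold on each side, 1 and 3 genes had the control in the middle. Repeated quantile normalization gave 518 and 408 lower than control (vector, siRNA), 9 with vector highest and 114 lower in both. Cyclic loess gave 129 and 85 lower, 7 with vector highest, 12 lower in both and 2 matrix genes higher. Centring gave 105 and 72 lower, 10 with vector highest and 9 lower in both. The filter at the 75th percentile, which tests fewer genes, gave 1021 higher and 113 lower (vector), 1016 higher (siRNA), 80 and 74 between the arms, 10 and 12 with control in the middle and 871 genes at least 2-fold higher in both arms. The mean over probe sets gave 143 lower (vector), 1020 and 131 (siRNA), 124 and 104 between the arms, 10 and 20 in the middle and 904 genes at least 2-fold higher in both arms, with COL6A1 at -0.040 for siRNA minus control. Without probe sets open to cross-hybridisation, 10 genes had vector highest, and siRNA minus control was -0.090 for BNIP3L, -0.31 for COL6A1, -0.17 for INSIG1 and -0.40 for TGFBR1, with -0.020 and -0.58 for INSIG1 and TGFBR1 in vector minus control. With vector minus siRNA in place of vector minus control, 0 matrix genes were higher. For the rest the cause was not tested. Spike-in centring was not run, a linear pseudocount does not apply to log2 values, and leaving out a sample was not possible. No paired analysis was possible because each group has 1 array. Signal over background limits WIF1 and other dim genes.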

Other observations

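Some members of other lists were higher than control in both arms, while the lists as a whole were not shifted. Over all 10917 genes kept, 15.2% were at least 2-fold higher than control in vector and 14.9% in siRNA cells. Counts of a few members therefore say little about a list. Of 18 sterol synthesis genes, whose medians were -0.083 in vector and -0.036 in siRNA cells (percentiles 56.6 and 65.8), 5 were at least 2-fold higher in each arm, SC5D (2.04 in vector and 2.08 in siRNA cells), HMGCS1 (1.47 and 1.87), IDI1 (1.20 and 1.39), INSIG1 (1.25 and 1.10) and MSMO1 (1.12 and 1.33). INSIG1 turned to -0.020 and -0.17 without probe sets open to cross-hybridisation, where IDI1 was at 0.97 in vector cells, and MSMO1 was at 0.83 there with the mean over probe sets. Of 14 heat shock genes 3 were higher in vector and 4 in siRNA cells, with HSP90AA1 at 2.32 and 2.15, and of 17 p53 target genes 5 and 4 were, with RRM2B at 2.47 and 2.32. With the mean over probe sets RRM2B (0.83 and 0.68), MDM2 (0.67 and 0.45) and TP53INP1 (0.22 and 0.68) missed 2-fold, while FAS in both arms and GDF15 in vector cells did not. Medians were 0.020 and -0.050 for the heat shock list (percentiles 68.5 and 49.8) and 0.32 and -0.019 for the p53 list (94.4 and 68.5), and the signs of the sterol medians and of the siRNA medians of the other lists turned with the scaling. Genes of zinc finger proteins named ZNF were chosen after their values were seen. Of 266 such genes, 74 (27.8%) were at least 2-fold higher in both arms, against 1313 of 10651 other genes (12.3%).

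Markers of other cell types were mostly below the filter. Of 15 fibroblast markers 1 was kept, MFAP5, and of immune, endothelial and glandular markers 5, 3 and 4 were. Among glandular markers, AGR2 was higher than control by 3.07 in vector and 1.57 in siRNA cells (0.78 there with the mean over probe sets), and ANXA10 was lower in vector than in siRNA cells (-2.18). Among genes of the unfolded protein and integrated stress responses, 21 of 24 were above 0 in vector minus siRNA, with a median of 0.21 (percentile 99.9) and none past 2-fold. G1/S genes had a median of -0.14 (percentile 0.12) over 29 genes in the same comparison, also with none past 2-fold. Immediate-early genes had a median of 0.23 over 20 genes there (percentile 99.8), with KLF4 past 2-fold (1.14).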
